A study of Mus musculus with 2 samples.

How the data were processed

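The data were unfiltered counts of unique molecular identifiers (UMIs) per gene and droplet barcode, deposited by the authors as 1 matrix for incisor tissue of untreated C57BL/6 mice of 4 weeks. Per the labels, lower incisors were freed of bone, pulp was isolated together with dental epithelium and digested with collagenase, and cells were barcoded with 10x Genomics 3′ v3 chemistry for a target of 10000 cells. Per the file headers, the deposited values are counts in metadata format version 2 made with software version 3.0.2, whose program is not named. Genome build mm10 and the tools R 3.4.1 and Seurat are given in the submitters' processing notes, but the aligner and the annotation release are not given in the sources used here. The 2 sample titles differed only in the lane (2 lanes) and no list linked barcodes to titles, so the matrix was treated as 1 sample, with no sample columns left unused (0). The matrix had 31053 genes, 6794880 barcodes and 68931830 UMIs, and its values were whole numbers up to 22771. Of the gene identifiers 30934 are in GENCODE M21, and 36 symbols that occurred more than once were kept apart by identifier.

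Barcodes with at least 500 detected genes and at most 20% of UMIs from 13 mitochondrial genes were kept (4775). Doublets were called with the scanpy implementation of Scrublet (expected share 5%, genes in at least 3 cells). Its automatic threshold called 1 barcode, so a score above 0.15 was used instead, which called 122 (2.55%). A further 114 barcodes (2.39%) outside erythroid clusters had more than 5% haemoglobin UMIs and were removed as possible pairs with red cells. Whether they were pairs or had taken up free haemoglobin RNA was not tested. The 4539 cells left had a median of 5792 UMIs, and no pair of columns was identical (0).

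Clustering scaled each cell to 10000 UMIs, took log1p values, 2000 variable genes scaled to a maximum of 10, 30 principal components and 15 neighbours, and used the Leiden method at resolution 1.0 with 10 iterations and seed 0. The fixed gene lists and the mitochondrial genes were left out of it. Mesenchymal cells were clustered again at resolution 0.5. Of 26 marker lists each step scored a part, and the list of cycling markers named no cluster. Mesenchymal clusters were scored on odontoblast, pulp, apical mesenchyme, follicle, osteoblast, perivascular, glial and chondrocyte lists only. Epithelial clusters were scored on ameloblast and stratum intermedium lists only. A cluster took the name of its best-scored list with at least 3 raised markers. No other family could have more of the cluster's 10 leading genes. Raised markers lay at least 2-fold over the median cluster and were present in at least 25% of the cluster's cells. Leading genes had the highest ratio to all other cells, with a CPM (counts scaled to the total) of 5 added to both sides, at least 100 UMIs and presence in at least 25% of cells. Of the markers 1 was missing from the matrix. Epithelial clusters were compared in the same way within the epithelium.

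Comparisons used summed counts per class or cluster as CPM, with exact Poisson intervals and log2 ratios with intervals from the exact conditional binomial. Shares have exact Clopper-Pearson intervals, all at 95%. With 1 sample no test between groups was made, and cells were not used as replicates. A gene with 0 counts on one side was given a bound from a floor of 3 counts over the group. Shares of cells with a UMI and shares with a Mki67 UMI were measured after thinning each cell to 2000 UMIs, and 691 cells below that depth were left out there. Macrophage-like and endothelial cells were chosen beforehand as cells that should lack Runx2 and Gli1. Droplets of 1 to 20 UMIs were taken as the level of free RNA, and whether they represent it was not tested.

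The 13 fixed lists (201 genes, 0 missing) were Runx, hedgehog, IGF, WNT, BMP and TGF-beta, FGF, Notch, mesenchymal stem cell markers, neurovascular ligands, immune and osteoclast ligands, mineralisation, dissociation response, and S phase and G2/M phase. They were fixed before the data were examined, as were the comparisons, the filters, the clustering settings, most alternatives and the rule for named genes. A listed gene was measured with at least 30 UMIs over both sides and counted as higher or lower at 2-fold. By the rule, the 2 to 4 members with the largest log2 ratio in either direction are named per list and comparison, together with Runx2, Gli1, Igf1, Igf2, Igfbp3, Igfbp5, Axin2 and Mki67, and up to 10 leading genes per class. For the smaller mesenchymal clusters only lists that stood out are given by name. The values of 1 listed gene are not reported. Among the listed genes 18 are also markers: Birc5, Bmp3, Cenpf, Cspg4, Ctsk, Fgf10, Fgf3, Igfbp3, Mcam, Mepe, Mki67, Notch3, Phex, Sfrp2, Sp7, Thy1, Top2a and Ube2c. List medians were compared with 10000 random lists of the same size, each member drawn from the 100 genes nearest in expression.

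Several choices were made after seeing the data. These were the doublet score threshold, the haemoglobin rule, the naming rule, the free RNA range, a requirement that a measured gene have an expected count of at least 3 on the smaller side, the interval rule for the highest class, and the singling out of the Ogn and Ccna2 clusters for the alternatives. The naming rule was the second tried, since the first called the Ogn cluster perivascular and the 2 unnamed clusters of few cells mast and T or NK. The band of at least 50 and under 1000 UMIs with more than 50% mitochondrial UMIs was also defined then, as was the median over genes used to test it for cell remnants. Alternatives tried were 200 and 1000 detected genes, 10% mitochondrial UMIs, doublets kept, 4000 variable genes, resolutions 0.5 and 2.0, the fixed lists kept in the clustering, seed 1, equal weight per cell, clustering on one part of the UMIs and measuring on the other, at least 100 UMIs per gene, other depths of thinning and at least 2 UMIs per positive cell. Added later were totals without genes above 1% of either side's UMIs, mesenchymal resolution 1.0, leaving out the Hbb-bs or the Ogn cluster, and the alternatives for the highest class.

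The procedure was tested on simulated data. A comparison was simulated at the UMI totals of epithelial and mesenchymal cells, with 12695 genes, 200 of them changed. Both sides were drawn with counting noise from the mesenchymal profile, so the high Amelx share of the real epithelium was absent. In it 95.2% of intervals held the true ratio and 0.408% of unchanged genes were called. Of genes changed by log2 −1.5, 96% were called on the right side, and 100% of those changed by 1.5, 3 or −3. Of unchanged lists 95.5% lay between percentiles 2.5 and 97.5. In simulated cells drawn from the profiles of the clusters found here, 97.5% were given the class they came from. The adjusted Rand index, which scores how well the clusters themselves were recovered, was 0.861. Neither simulation held doublets or differences between cells beyond counting noise, so real cells may be named less well.

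Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Barcodes outside the filters were used only for free RNA and for the low-count barcodes described at the end.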

Results

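Cells of the mouse lower incisor were profiled by droplet single-cell RNA sequencing. The incisor grows throughout life, so its proximal end holds dividing epithelial and mesenchymal cells beside their differentiating descendants. The labels describe untreated C57BL/6 animals of 4 weeks and call the tissue dental mesenchyme, whereas the protocol kept the dental epithelium with the pulp. The 2 sample titles differed only in the lane, and the deposited counts were a single matrix without a map from barcodes to titles. The matrix was therefore treated as 1 sample, so the number of animals behind it is unknown and no difference below has a replicate check. Intervals are exact 95% intervals (Clopper-Pearson for shares, Poisson for counts and their ratios) and cover counting error only.

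The matrix held 68931830 unique molecular identifiers (UMIs) over 31053 genes, and 1546436 of its 6794880 barcodes had at least 1 UMI. Of these barcodes, 5336 had at least 500 detected genes, beside a stated target of 10000 recovered cells. A mitochondrial share above 20% removed 561 barcodes, and doublet calls removed 122 by simulated doublets and 114 by haemoglobin RNA, which left 4539 cells with 50.3% of all UMIs. The median cell had 5792 UMIs (quartiles 2863 and 9198), 1876 detected genes and a mitochondrial share of 7.21%.

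The first question was which cell types the dissected tissue held. Mesenchymal cells were the largest class, followed by immune cells and by epithelium, and endothelial cells were rare. Clusters were named by marker lists, so the genes that name a class are its definition and not a result. The mesenchymal class had 2203 cells, 48.5% of all (47.1 to 50.0004). Epithelial cells were 16.9% (15.9 to 18.1), with 769 cells that included ameloblast-like clusters with the enamel matrix genes Amelx and Ambn. Immune cells were 28.3% (27.0 to 29.6). The immune class consisted of macrophage- or monocyte-like cells (14.0% of all cells), B cells (4.54%), neutrophils (4.16%), dendritic cells (3.90%) and T or NK cells (1.65%). Macrophage clusters were led by Ccl7, Mrc1, C1qa and Ly6c2 among others. Endothelial cells, led by Emcn, Plvap, Cdh5 and Kdr, were 1.63% (1.28 to 2.04). Erythroid cells were 2.09%, and 114 cells stayed unnamed. Of these, 76 formed a Gzma cluster whose leading genes included Nkg7, Gzmb and Klrd1, genes of cytotoxic lymphocytes, and they are not counted in the immune or the T or NK share. The other 38 formed an Hs3st1 cluster. Chondrocyte, glial, lymphatic endothelial, mast, neuronal, osteoclast, perivascular and skeletal muscle names were given to no cluster. This does not exclude such cells, since a few of them inside another cluster would not be seen. For perivascular cells the limit is wider, since it stays open whether the whole Ogn cluster described below is perivascular-like. Depth differed between classes, with a median of 9304 UMIs in epithelial, 7005 in mesenchymal, 4495.5 in endothelial and 3089 in immune cells. Shares moved with the filters: the immune share was 19.2% when cells needed 1000 detected genes.

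**Figure D1:**
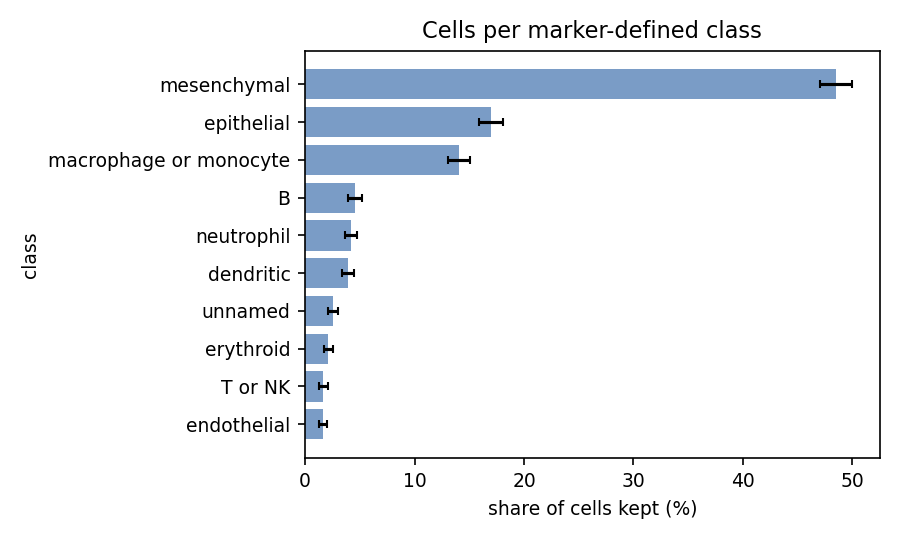
Share of the 4539 cells in each marker-defined class, in percent; bars are shares and error bars exact 95% intervals of counting error. Mesenchymal cells reach 48.5%, epithelial cells 16.9% and macrophage- or monocyte-like cells 14.0%.

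The labels name mesenchyme alone, so the second question was which signalling and differentiation genes separated the epithelium from the mesenchyme in the same tissue. Ligands were divided between the layers. Epithelial cells held Shh, Wnt4, Fgf9 and the Notch ligands Jag1 and Jag2, while mesenchymal cells held Igf1, Fgf3, Fgf10, Bmp3, Cxcl12 and most secreted WNT antagonists. The hedgehog target Gli1 was at a similar level in both. Of 183 listed genes with enough UMIs, 26 were at least 2-fold higher and 74 at least 2-fold lower in epithelial cells. The enamel gene Amelx alone took 15.9% of epithelial UMIs and Ambn 2.47%, and this pushed all other genes down: the median log2 ratio of 12920 genes was −0.29. It was 0.01 when the 5 genes above 1% of either side's UMIs were left out of the totals, and then 31 listed genes were higher and 57 lower. Medians of lists below are given with all UMIs first and with those reduced totals second. The listed genes had been kept out of the clustering, but 18 of the 201 also served in naming clusters, among them Bmp3, Fgf3, Fgf10, Igfbp3, Mki67, Phex, Sfrp2 and Sp7.

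WNT genes showed the widest division. Of 19 measured members 15 were lower and 2 higher in epithelial cells, with a median log2 ratio of −4.19 (−3.89 with reduced totals, with 13 lower and 3 higher), below every one of 10000 random lists of like expression. The WNT antagonists Dkk2 (3 epithelial UMIs, log2 −6.97, −9.26 to −5.42), Notum (2.66 against 302 CPM, counts scaled to the class total) and Sfrp2 (2.27 against 214 CPM) were mesenchymal. The ligand Wnt4 was epithelial, at 156 against 4.06 CPM (log2 5.26, 4.92 to 5.62), as was Wnt6 (log2 1.15, 1.06 to 1.25). Axin2, a target of the pathway, was lower in epithelial cells by this measure (log2 −1.21, −1.54 to −0.90), yet within 2-fold with reduced totals (−0.92).

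In the hedgehog list 3 of 12 members were higher and 3 lower, and the median changed sign with the totals (−0.17 and 0.13). The ligand Shh had 302 CPM in epithelial and 1.45 CPM in mesenchymal cells (log2 7.71, 7.15 to 8.32). Its antagonist Hhip was mesenchymal, with 3 epithelial UMIs (log2 −8.17, −10.44 to −6.62). The coreceptor Cdon was epithelial (log2 3.6, 2.75 to 4.56). The receptor gene Ptch1 was lower in epithelium (log2 −1.72, −1.80 to −1.64). Gli1 stood at 43.8 and 37.6 CPM (log2 0.22, 0.05 to 0.40). The Runx list was small, with 4 measured members, 1 higher and 1 lower, and a median of −0.92 (−0.62). Runx1 was the epithelial member, at 144 against 14.1 CPM (log2 3.35, 3.15 to 3.55), and Runx2, the regulator of osteoblast and odontoblast lineages, was the mesenchymal one, at 11.9 against 97.2 CPM (log2 −3.03, −3.31 to −2.76).

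Insulin-like growth factor (IGF) genes leaned to the mesenchyme, with 5 of 10 members lower and 2 higher and a median of −1.43 (−1.14). Igf1 had 3.35 CPM in epithelial and 328 CPM in mesenchymal cells (log2 −6.61, −7.14 to −6.13), and the binding protein Igfbp6 followed (log2 −4.78). Outside the Ogn cluster described below, mesenchymal cells had 9.59 CPM of Igf1. Igf2 was scarce on both sides, at 1.08 and 4.90 CPM (log2 −2.18, −3.23 to −1.27). Igfbp5 was higher in epithelium, at 168 against 72.3 CPM (log2 1.21, 1.11 to 1.32), as was Igfbp2 (log2 2.5). Most epithelial Igfbp5 UMIs (1202 of 1704) came from the 93 cells of the Krt17 cluster. The rest of the epithelium had 54.4 CPM of Igfbp5, less than the mesenchyme as a whole. Mesenchymal Igfbp5 was likewise uneven, since most of its UMIs came from the Ogn cluster described below. Mesenchymal cells outside that cluster had less Igfbp5 than the rest of the epithelium. Igfbp3 was within 2-fold at 129 and 187 CPM (log2 −0.54, −0.63 to −0.44), but not when each cell was weighted equally (−1.33). Igfbp5, by contrast, came to 0.79 with equal weights, within 2-fold. Mesenchymal cells outside the Ogn cluster had 9.19 CPM of Igfbp3, far less than the epithelial class.

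Growth factors of the BMP, FGF and Notch families were each split. In the BMP and TGF-beta list 5 of 20 members were lower and 2 higher (median −0.46 and −0.16), and 4 were higher with reduced totals. Bmp3 had 0.887 epithelial and 52.6 mesenchymal CPM (log2 −5.89, −7.02 to −4.96) and Bmp5 was likewise mesenchymal (log2 −4.59), whereas Tgfbr3 was epithelial (log2 2.01). FGF genes had 7 of 14 members lower and 2 higher (median −0.69 and −0.40), and 5 were lower with reduced totals. Fgf10 had 2 epithelial UMIs (log2 −6.99, −10.04 to −5.13) and Fgf3 0.788 against 48.2 CPM, while Fgf9 was epithelial at 11.9 against 0.445 CPM (log2 4.74, 3.72 to 5.99). For the Notch list 5 of 12 members were higher and 4 lower (median 0.12 and 0.41), which became 6 and 2 with reduced totals. Its ligands Jag2 (102 against 1.89 CPM, log2 5.76) and Jag1 (81.1 against 15.4 CPM, log2 2.40) were epithelial, as was the feedback gene Nrarp (log2 3.49), and the endothelial ligand Dll4 was lower (log2 −2.01, −3.40 to −0.86).

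Of the genes used as mesenchymal stem cell markers 10 of 15 were lower in epithelium and 2 higher (median −1.21 and −0.92), but 7 were lower with reduced totals. Cxcl12 had 0.690 against 63.9 CPM (log2 −6.53, −7.85 to −5.49) and the protease gene Ctsk had a log2 ratio of −5.69, while the planar polarity gene Celsr1 was epithelial (151 against 17.6 CPM, log2 3.10). Among neurovascular ligands 7 of 10 were lower and 1 higher (median −2.41 and −2.11). The axon guidance gene Ntn1 had 1 epithelial UMI (log2 −7.29, −12.60 to −4.80), and the exception was the growth factor Pdgfa (95.5 against 19.9 CPM, log2 2.27). Immune and osteoclast ligands had 5 measured members, 1 higher and 1 lower (median −0.79 and −0.49), and Kitl, the ligand of the receptor Kit, was the higher one (33.2 against 5.01 CPM, log2 2.73). Mineralisation genes had 6 of 11 members lower and 2 higher (median −1.06 and −0.76), and 5 were lower with reduced totals. Phex, an endopeptidase of odontoblasts and osteoblasts, had 3 epithelial UMIs (log2 −5.83, −8.11 to −4.27) and Enpp1 a log2 ratio of −2.97. The osteoblast regulator Sp7 was mesenchymal (24.3 against 137 CPM) and the dental epithelial regulator Sp6 was higher in epithelium (620 against 195 CPM, log2 1.67).

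Of the cell cycle genes 12 of 40 were lower and 0 higher in epithelial cells (median −0.83 and −0.53), but 4 were lower with reduced totals. Ccnb1 (log2 −1.38, −1.58 to −1.19) and Mcm3 (log2 −1.35, −1.66 to −1.04) were the lowest. Mki67, a gene of dividing cells, was within 2-fold at 46.3 and 67.9 CPM (log2 −0.55, −0.71 to −0.40) and reached −2.16 at clustering resolution 2.0, at which the epithelial class had 13.9% of cells. Genes of the dissociation response ran the other way, with 3 of 14 higher and 0 lower (median 0.43 and 0.73, percentile 99.8 of random lists, and 4 higher with reduced totals), led by Atf3 (72.6 against 5.79 CPM, log2 3.65) and Btg2 (log2 1.63). The design does not separate a difference between the layers from one in their response to digestion.

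**Figure D2:**
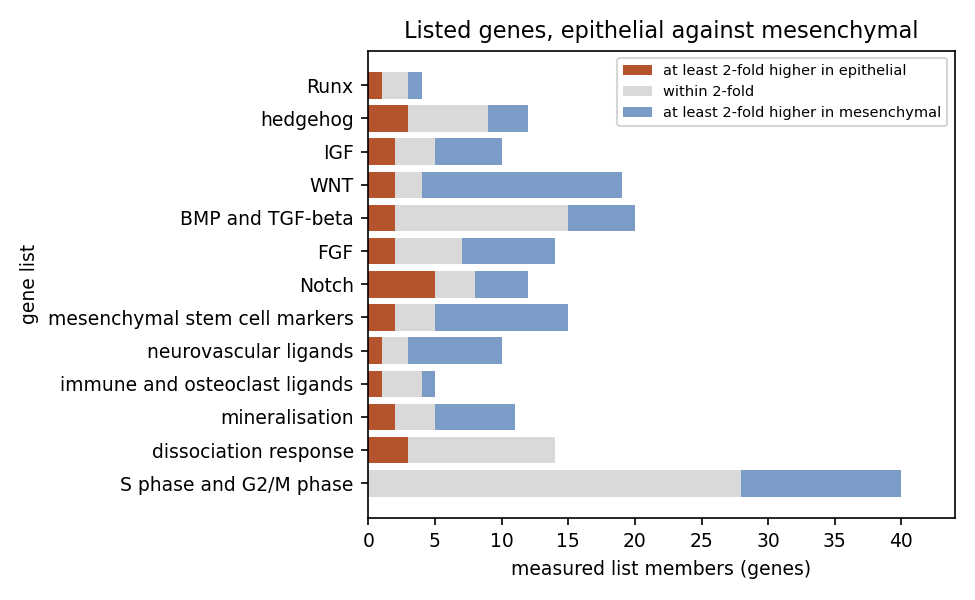
Number of measured genes of each fixed list (bars, in genes) at least 2-fold higher in epithelial cells, within 2-fold, or at least 2-fold higher in mesenchymal cells, from CPM over all UMIs. In the WNT list 15 of 19 genes lie on the mesenchymal side, and in the dissociation response list 0 of 14 do.

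Within the mesenchyme the question was which clusters held the signalling genes, since these had been kept out of the clustering. Clustering the 2203 mesenchymal cells again gave 9 clusters, each called here by its leading gene outside the lists. Among them were odontoblast-like cells, a cluster high in cell cycle genes, a cluster with follicle markers and contractile genes, and several others that met no naming rule. The Fmod cluster was the largest, with 19.6% of mesenchymal cells, and was led by the matrix genes Fmod, Col9a2 and Vcan. The Ogn cluster had 384 cells, 17.4% (15.9 to 19.1), and was led by Ogn, Tagln, Dpep1 and Acta2. It raised 4 dental follicle, 2 apical mesenchyme, 2 perivascular and 1 pulp markers and stayed unnamed. The Sct cluster (17.0%; Sct, Col24a1, Ifitm5) and the small Dspp cluster (22 cells, 0.999%, 0.627 to 1.51; Dspp, Bglap, Ibsp) were named odontoblast-like. Further clusters were led by Ccna2 (16.3%), Lypd1 (10.3%; also Col8a2, Sostdc1 and Foxd1), Tac1 (8.13%; also Coch and Cxcl14) and Cldn10 (6.40%; also Stbd1 and Vim). The Hbb-bs cluster (3.90%) had a median of 1928.5 UMIs and 0 of 136 listed genes at least 2-fold higher.

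Listed genes gathered most clearly in the Ogn cluster, which had 51 of 178 measured genes at least 2-fold above the other mesenchymal cells and 39 below. It held nearly all the IGF genes of the mesenchyme, Runx2, several secreted antagonists of the WNT and hedgehog pathways, and ligands for vessels and nerves. Most mineralisation genes were lower in it. Gli1 and Axin2 were within 2-fold of their level in the pooled other mesenchymal cells, as was Mki67, although the latter varied widely among those cells and within the cluster. Of the IGF genes 9 of 10 were higher and 0 lower (median log2 4.47). Igf1 had 2091 CPM against 9.59 CPM (log2 7.77, 7.53 to 8.02). The binding proteins Igfbp3 (1175 against 9.19 CPM, log2 6.998, 6.75 to 7.25), Igfbp5 (449 against 4.33 CPM, log2 6.69, 6.34 to 7.07) and Igfbp2 (log2 6.92, 5.65 to 8.57) were of like size, and Igf2 was higher at 21.5 against 1.90 CPM (log2 3.49, 2.83 to 4.19). Runx2 had 379 against 46.4 CPM (log2 3.03, 2.89 to 3.17), while Runx1 was lower (log2 −1.002, −1.72 to −0.36), which left the Runx list with 1 of 4 higher and 1 lower (median −0.40). At mesenchymal resolution 1.0 the Ogn cells formed an Acta2 part of 239 cells and a Spock1 part of 145, both with high Runx2 (403 and 340.0 CPM), Igf1 (2602 and 1268 CPM) and Igfbp3 (907 and 1607 CPM). With the Acta2 part alone against all other mesenchymal cells, Spock1 cells included, the log2 ratios were 2.62 for Runx2, 4.84 for Igf1, 3.01 for Igfbp3, 4.42 for Igfbp5 and −4.66 for Mki67, and 72 listed genes were lower in place of 39.

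Pathway lists of the Ogn cluster mostly held genes of both directions. In the hedgehog list 4 of 10 members were higher and 0 lower (median 0.65), led by the antagonist Hhip (495 against 10.7 CPM, log2 5.53) and the coreceptor Gas1 (141 against 12.6 CPM, log2 3.48), whereas Gli1 stood at 40.02 and 37.2 CPM (log2 0.11, −0.20 to 0.40). The WNT list had 10 of 19 higher and 5 lower (median 1.27). Dkk2 (233 against 1.77 CPM, log2 7.04) and Sfrp2 (1291 against 19.5 CPM, log2 6.05) were higher, while Notum (4.00 against 356 CPM, log2 −6.48) and the ligand Wnt6 (log2 −5.91) were lower and Axin2 was within 2-fold (21.5 against 23.6 CPM, log2 −0.14, −0.56 to 0.26). For BMP and TGF-beta genes 6 of 20 were higher and 4 lower (median 0.00). Bmp3 (327 against 3.09 CPM, log2 6.73) and the antagonist Nog (log2 3.25) were higher, and the BMP target Id1 lower (log2 −2.70, −3.01 to −2.41). FGF genes were mainly lower, 8 of 12 against 2 higher (median −1.75), with Fgf3 at 2.18 against 56.5 CPM (log2 −4.69) and the receptor Fgfr2 at 198 against 12.3 CPM (log2 4.00). Of the Notch genes 3 of 11 were higher and 4 lower (median 0.11): Notch1 was higher (log2 1.99) and Dll1, with 0 UMIs against 13.1 CPM, had a log2 ratio of at most −3.59.

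Stem cell markers and ligands for other tissues were also high in this cluster. Among the stem cell markers 8 of 15 were higher and 3 lower (median 1.61), with Cxcl12 at 374 against 7.88 CPM (log2 5.57) and Ly6a with 2 UMIs in all other clusters (log2 7.42, 5.51 to 10.50), although Thy1 was lower (log2 −2.999). Neurovascular ligands had 7 of 10 members higher and 1 lower (median 2.83), above every random list. Ntn1 had 98.6 against 0.394 CPM (log2 7.97, 6.83 to 9.43), and the vessel growth factors Vegfc (log2 6.499) and Angpt1 (103 against 3.61 CPM, log2 4.83) followed. Of 5 immune and osteoclast ligands 2 were higher and 1 lower (median 0.35): the macrophage growth factor Csf1 was higher (log2 1.53, 0.99 to 2.06) and Kitl lower (log2 −1.10, −2.46 to 0.01). In the mineralisation list 0 of 11 were higher and 8 lower (median −1.72), with 1 Phex UMI in the cluster (log2 −5.76, −11.07 to −3.27), Sp6 at 12.4 against 228 CPM (log2 −4.20) and Dlx3 at 28.4 against 196 CPM (log2 −2.79). None of the 14 dissociation genes differed by 2-fold (median 0.17). Of 40 cell cycle genes 4 were lower, among them Ung (log2 −2.01), and 0 higher (median −0.49), and Mki67 stood at 57.1 and 69.9 CPM (log2 −0.29, −0.54 to −0.05).

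**Figure D3:**
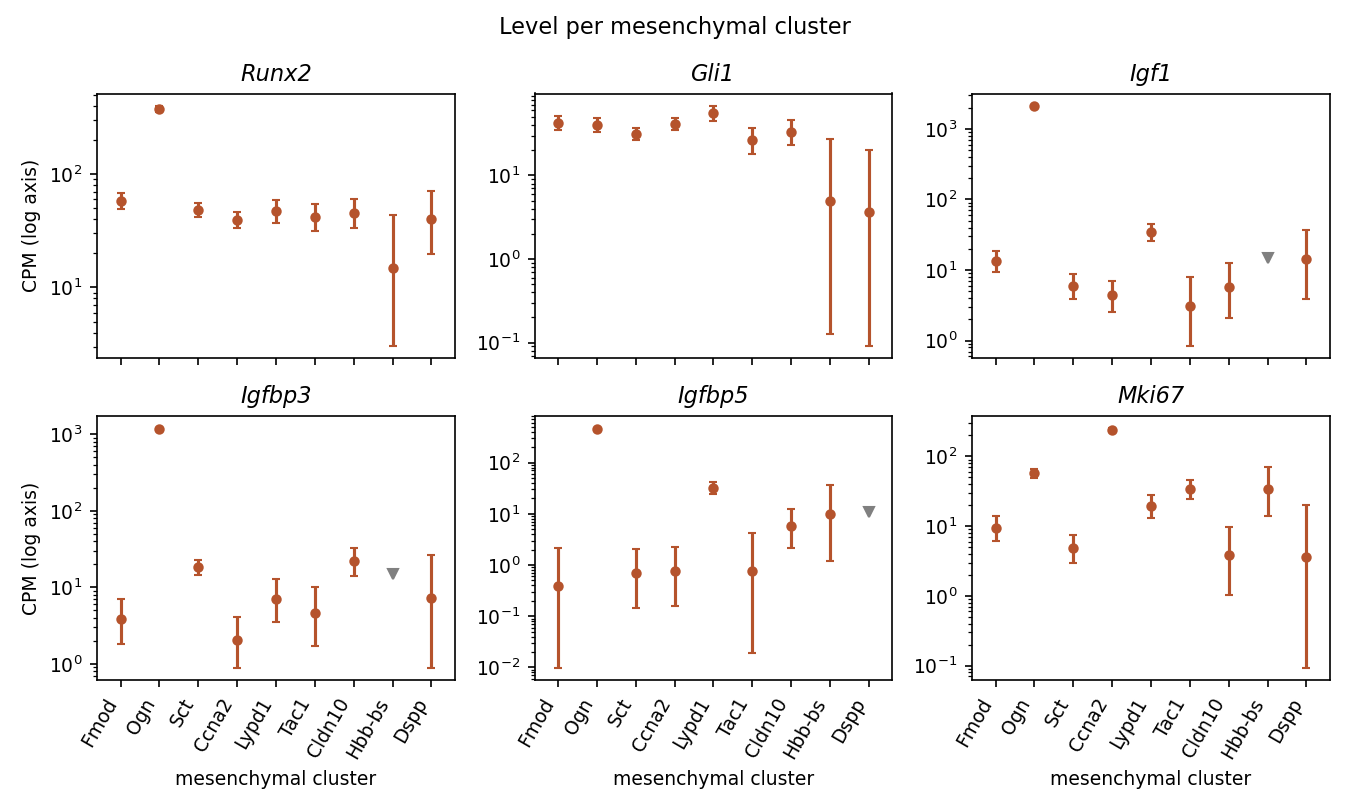
Level of 6 genes in each mesenchymal cluster, in CPM of the summed counts on a log axis; points are levels, error bars exact 95% Poisson intervals, and grey triangles the level of 3 UMIs for clusters with 0. Runx2 reaches 379 CPM in the Ogn cluster against 14.8 to 58.3 CPM elsewhere, while Gli1 spans 26.3 to 55.5 CPM in the 7 clusters of more than 100 cells.

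The odontoblast-like clusters were each compared with all other mesenchymal cells and not with each other. Those other cells include the Ogn and Ccna2 clusters and, for the small Dspp cluster, the Sct cells. Mineralisation genes were higher in the Sct cluster in 6 of 11 cases and lower in 1 (median 1.22), with Phex at 51.4 against 5.73 CPM (log2 3.17, 2.79 to 3.56), Enpp1 at log2 2.99 and the pyrophosphate transporter gene Ank at 321 against 61.4 CPM (log2 2.39). The antagonist Dkk1 had 936 CPM there against 58.1 CPM (log2 4.01, 3.90 to 4.12), and the Notch ligand Dll1 33.0 against 4.11 CPM (log2 3.01). Fgf10 (52.5 against 16.3 CPM, log2 1.69) was higher and Fgfr2 lower (log2 −3.93). Cell cycle genes were lower in 38 of 40 cases (median −2.89) and IGF genes in 8 of 10. Both lists were also low in the Cldn10 cluster, with 36 of 40 and 7 of 10 genes lower and 0 higher. The Dspp cluster, with the bone matrix genes Bglap and Ibsp among its leading genes, had 2 of 11 mineralisation genes higher and 3 lower (median −0.17). Phex stood there at 235 against 13.4 CPM (log2 4.13, 3.71 to 4.53) and the intermediate filament gene Nes at 184 against 27.5 CPM (log2 2.75). Of the mineralisation genes, Phex and Sp7 are also odontoblast markers used for naming, so their levels in both clusters are not independent of the names. Dissociation genes were higher in 11 of 13 cases in the Dspp cluster (median 1.82) and in 4 of 14 in the Sct cluster (median 0.71). Fos, for one, had 1247 against 180 CPM in the Dspp cluster (log2 2.79), and the design does not separate the state of these cells from their response to digestion.

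In the remaining clusters many more listed genes were lower than higher, against other mesenchymal cells that include the Ogn and Ccna2 clusters. The counts were 80 lower and 11 higher in the Cldn10, 66 and 11 in the Tac1, 70 and 13 in the Lypd1 and 86 and 4 in the Fmod cluster. In the Cldn10 cluster 5 of 8 measured Notch genes were higher and 0 lower (median 1.35), with the Notch targets Heyl (46.8 against 1.42 CPM, log2 5.04, 4.31 to 5.81) and Hey1 (201 against 25.05 CPM, log2 3.01) and the receptor Notch3 (log2 2.51). It also held the phosphate transporter Slc20a2 (251 against 24.9 CPM, log2 3.34) and the phosphatase Alpl (949 against 156 CPM, log2 2.61). The Tac1 cluster had low hedgehog genes, 5 of 10 being lower and 0 higher. Hhip had 0 UMIs there against 91.4 CPM elsewhere (log2 at most −5.30), and the hedgehog receptor and target Ptch1 63.4 against 491 CPM (log2 −2.95, −3.28 to −2.64). In the Lypd1 cluster Fgf3 (93.7 against 43.9 CPM, log2 1.09) and the vessel growth factor Vegfd (log2 1.95, 1.38 to 2.49) were higher, while 11 of 19 WNT genes were lower, and of 40 cycle genes 22 were lower and 7 higher. In the Fmod cluster the receptor Fgfr3 was higher, at 58.7 against 16.1 CPM (log2 1.87, 1.57 to 2.16), while 14 of 19 WNT genes and 26 of 40 cycle genes were lower.

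Whether cells with Gli1 RNA also held Runx2 RNA was asked in cells thinned to 2000 UMIs, so that depth was equal. Gli1 UMIs were spread over the mesenchymal clusters and Runx2 UMIs were concentrated in the Ogn cluster. Of 2032 mesenchymal cells, 159 had a Gli1 UMI, 7.82% (6.69 to 9.08), and 349 a Runx2 UMI, 17.2% (15.6 to 18.9). Macrophage- or monocyte-like cells, set beside them as cells that should lack both genes, had a Runx2 UMI in 17 of 519, 3.28% (1.92 to 5.19), and a Gli1 UMI in 1 of 519 (0.193%). Droplets of 1 to 20 UMIs had similar levels of both genes (15.3 CPM of Runx2 and 11.5 CPM of Gli1). Free RNA like theirs would therefore not part these shares, and the Runx2 share in macrophages is an upper limit of its background. The macrophage- or monocyte-like cells had a median depth before thinning of 4730 UMIs, beside 7357.5 in mesenchymal cells. Endothelial cells had neither in 66 cells (interval up to 5.44%, median depth 4634.5). A Gli1 UMI was present in 8.71% of epithelial cells (6.74 to 11.02) and a Runx2 UMI in 1.83% (0.976 to 3.10), so whether the Runx2 UMIs of the whole epithelial class exceed background is not settled. The Krt17 epithelial cluster had Runx2 at 66.6 CPM, above the level in droplets of 1 to 20 UMIs. Runx2 was detected in 32 of 159 Gli1-positive mesenchymal cells, 20.1% (14.2 to 27.2), and in 317 of 1873 Gli1-negative cells, 16.9% (15.3 to 18.7). The intervals overlap, and no test of the difference was made. Its direction turned at 1000 UMIs, with 7.87% (7 of 89 cells, 3.22 to 15.5) and 9.57%, and the unthinned shares were 43.9% and 35.2%. The thinned shares come from a single random draw per depth.

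By cluster, Runx2 detection was 54.7% in Ogn cells (49.4 to 59.99) and between 6.90% and 11.3% in the other 6 clusters of more than 100 cells. Among Ogn cells it was 58.1% (39.1 to 75.5) with a Gli1 UMI and 54.4% (48.9 to 59.9) without. Leaving out the Ogn cluster gave 10.9% of Gli1-positive and 8.99% of Gli1-negative mesenchymal cells. Gli1 detection was highest in Lypd1 cells, at 13.3% (9.002 to 18.6), and 8.66% in Ogn cells.

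**Figure D4:**
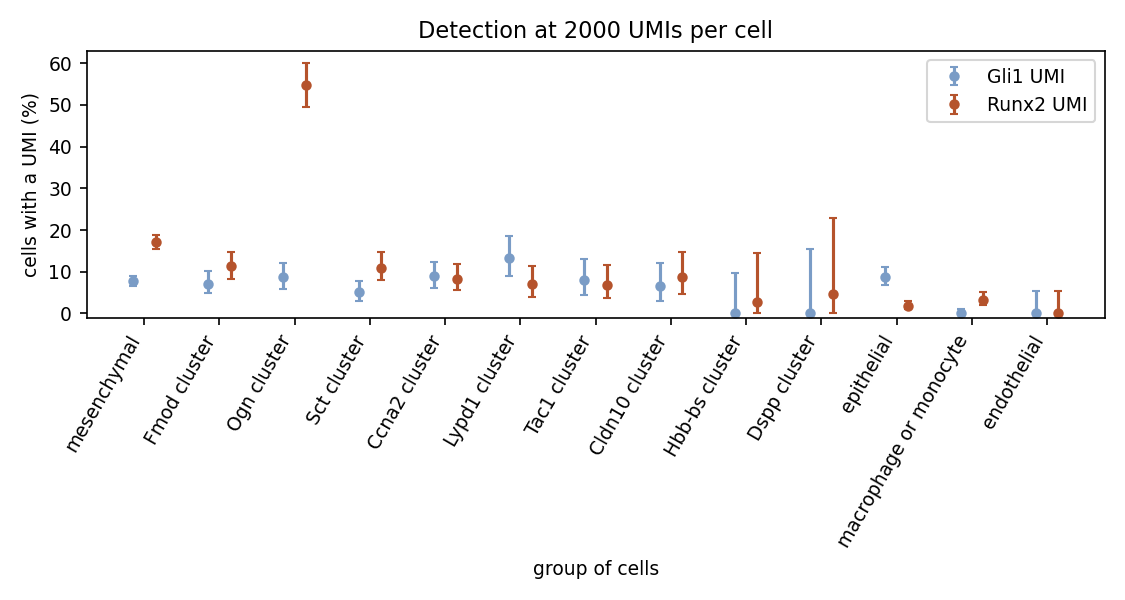
Share of cells with a Gli1 or a Runx2 UMI after thinning each cell to 2000 UMIs, in percent, for all mesenchymal cells, the 9 mesenchymal clusters and 3 other classes; points are shares and error bars exact 95% intervals. Runx2 detection reaches 54.7% in the Ogn cluster and 3.28% in macrophage- or monocyte-like cells.

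Many dividing cells formed a cluster of their own, but cells with a Mki67 UMI were also found in other clusters. The listed cycle genes had been withheld from the clustering, but other cycle genes had not, and these (Ccna2, Cdca8, Racgap1) led the cluster, so a high level of the listed genes in it follows from its definition. The Ccna2 cluster had 58.4 UMIs of cycle genes per 10000 (57.6 to 59.1) and a Mki67 UMI in 34.5% of thinned cells (29.5 to 39.7). It was followed by the Tac1 (16.6 per 10000), Ogn (14.3) and Lypd1 (13.5) clusters. A Mki67 UMI was present in 5.17% of thinned Tac1 cells and 5.59% of thinned Ogn cells. The Sct (4.24), Cldn10 (3.82) and Dspp (3.62) clusters were lowest, and Mki67 was found in 0.563% of Sct cells (0.0683 to 2.02). In the Ccna2 cluster 38 of 40 cycle genes were at least 2-fold higher and 0 lower (median 3.05), with Plk1 (36.1 against 2.27 CPM, log2 3.99), Ube2c (695 against 43.7 CPM, log2 3.99) and Mki67 (log2 3.55, 3.36 to 3.75) among the leaders. Fgf3 was also higher in these cells (90.3 against 36.6 CPM, log2 1.30), and Alpl lower (log2 −2.51). Outside the mesenchyme, erythroid cells had 51.0 cycle UMIs per 10000, B cells 34.4 and macrophage- or monocyte-like cells 15.8.

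The last question was which class held each listed ligand and receptor. Mesenchymal cells were the main holders of WNT and mineralisation genes, endothelial cells of Notch genes, and macrophages of dissociation response genes. For 122 of 185 measured genes the highest class exceeded the next beyond the counting interval, 46 of them in mesenchymal, 23 in endothelial, 16 in epithelial and 15 in macrophage- or monocyte-like cells. These counts use all UMIs, of which 5 dominant genes took 22.1% in epithelial and 4.34% in mesenchymal cells. Narrow leads between these layers depend on this. Smo, for one, was 1.14 times higher in mesenchyme but slightly higher in epithelium with reduced totals (log2 0.11). Mesenchymal cells led for 13 of 19 WNT genes, as for Sfrp2 (214 CPM, 11.9 times the next class, 9.14 to 15.9), and for 8 of 11 mineralisation genes, as for Sp7 (5.63 times, 4.94 to 6.45). Runx2 was mesenchymal with dendritic cells next (2.34 times, 1.62 to 3.50), Igf1 mesenchymal with macrophages next at 168 CPM (1.95 times, 1.78 to 2.14), and Igf2 mesenchymal (4.52 times, 2.41 to 9.38). Endothelial cells led for 6 of 12 Notch genes, as for Dll4 (94.3 CPM, 4.69 times, 2.51 to 9.31). They also had Igfbp7 (3558 CPM, 20.4 times), Igfbp3 (837 CPM, 4.47 times the mesenchymal level), Kitl (5.81 times the epithelial level) and Cxcl12 (233 CPM, 3.65 times). These are leads over whole classes: within the mesenchyme the Ogn cluster had more Igfbp3 (1175 CPM) and Cxcl12 (374 CPM) than endothelial cells. Mesenchymal cells outside that cluster had 46.4 CPM of Runx2, near the 41.6 CPM of dendritic cells. Their Igf1 level of 9.59 CPM was below that of macrophages. Epithelial cells led for Shh (23.2 times, 12.6 to 48.4), Wnt4 (29.6 times, 5.31 to 1170) and, narrowly, Gli1 (1.17 times, 1.03 to 1.32). Macrophages led for the chemokines Ccl2 (5289 CPM, 10.2 times) and Cxcl1 (7.56 times) and for 10 of 14 dissociation genes. Mki67 was highest in erythroid cells (1.87 times the B cell level). Igfbp5 (1.10 times, 0.863 to 1.42) and Axin2 (1.36 times, 0.495 to 2.98) had no class clearly above the next.

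The genes named throughout were identified by the gene table of the deposited matrix, and their positions are those of GENCODE M21 on GRCm38 (mm10). Runx2 (ENSMUSG00000039153) lies on chromosome 17 from 44495987 to 44814797, and Gli1 (ENSMUSG00000025407) on chromosome 10 from 127329882 to 127341974. Igf1 (ENSMUSG00000020053) lies on chromosome 10 from 87858265 to 87937042, Igf2 (ENSMUSG00000048583) on chromosome 7 from 142650766 to 142666816, and Igfbp3 (ENSMUSG00000020427) on chromosome 11 from 7206086 to 7213923. Igfbp5 (ENSMUSG00000026185) is on chromosome 1 from 72857932 to 72874884, Axin2 (ENSMUSG00000000142) on chromosome 11 from 108920349 to 108950783, and Mki67 (ENSMUSG00000031004) on chromosome 7 from 135689784 to 135716361.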

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

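The tests of free RNA below, and the UMI range and the median used in the tests of cell remnants, were chosen after the data were seen. Barcodes too small to count as cells carried a large mitochondrial signal that none of the comparisons used. Of 62775 barcodes with at least 50 and under 1000 UMIs, 55230 (88.0%) had more than 50% mitochondrial UMIs, which came to 75.8% of all UMIs in that range. Kept cells had a median of 7.21%.

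Free RNA in the droplets is argued against as the source, since droplets of 1 to 20 UMIs had 30.7% mitochondrial UMIs, which is 45.1 percentage points less. Whether these barcodes are remnants of single cells that lost their cytoplasm could not be decided. Over 56 class marker genes the median variance to mean ratio of counts per barcode was 1.12, and remnants simulated from the classes at the same depth would give 1.05. The bound of 1.5 set beforehand for RNA mixed from all cells was therefore wrong, because both cases lie below it at so few UMIs per barcode. A ratio above 2 was seen for 8 genes, beside 11 in the simulation. Damaged cells thus may be part of the signal, and no biological explanation was tested, as the design has 1 group.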

How the results depend on the processing

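Tests without dominant genes, at mesenchymal resolution 1.0, without the Hbb-bs or the Ogn cluster, and those of the highest class were chosen after the results were seen. No paired analysis was possible because there was 1 pooled sample, and for the same reason no leave-one-out was possible. Among 159 recomputed values of the principal results 127 stayed within their interval or within 1.5 times their count, and 32 moved, and among 222 values of single genes 193 stayed and 29 moved. None of these single-gene ratios of at least 2-fold changed sign, but the Gli1 ratio of the Ogn cluster, within 2-fold, ranged from log2 −0.13 to 0.21, and the order of the Runx2-positive shares turned at 1000 UMIs. The Runx2 ratio of the Ogn cluster ranged from log2 2.62 to 3.08 and that of epithelial over mesenchymal cells from −3.32 to −2.73, and the genes higher in the Ogn cluster numbered 40 to 56. With at least 200 detected genes the mesenchymal share was 46.1%, the immune share 32.5% and the cycle UMIs of the Ccna2 cluster 59.8 per 10000. With 1000 genes the mesenchymal, epithelial and immune shares were 50.7%, 19.2% and 19.2%, and Runx2-positive cells were 19.0% of Gli1-negative ones. At 10% mitochondrial UMIs the 3 shares were 54.8%, 19.6% and 22.4%, and cycle UMIs 57.6. These filters change which cells enter, and immune cells were the shallowest of the 3 classes. With doublets kept the immune share was 24.8% and cycle UMIs 59.3. With 4000 variable genes the mesenchymal share was 45.2% and cycle UMIs 61.7. At resolution 0.5 the immune share was 30.0%, and at 2.0 the epithelial share was 13.9%, the immune share 25.6% and cycle UMIs 60.1. With the fixed lists kept in the clustering the mesenchymal share was 42.9%, the immune share 25.4% and cycle UMIs 62.6. With seed 1 cycle UMIs were 60.2. For changes in the doublets, variable genes, resolution, lists and seed the cause was not tested. Depth per cell sets detection by construction: Runx2-positive shares of Gli1-positive and Gli1-negative cells were 7.87% and 9.57% at 1000 UMIs and 43.9% and 35.2% without thinning. At 2 or more UMIs the share was 32.4% of Gli1-positive cells, and Mki67 was seen in 20.3% of Ccna2 cells at 1000 UMIs. Without the Ogn cluster, which held most Runx2 UMIs, the shares were 10.9% and 8.99%. At mesenchymal resolution 1.0, which splits the Ogn cells, 72 listed genes were lower in place of 39.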

Other observations

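The test of Ambn and Amelx below was chosen after the result was seen, as was the comparison of the epithelial clusters. Predictions for the Ogn cluster were written before their tests were run. The choice of that cluster and the free RNA range, however, came after the data were seen. The comparison of its Igf1 level with macrophages and its Runx2 share at full depth were not among the predictions. The epithelium divided into 4 clusters that were not part of any planned comparison. A cluster high in cell cycle genes, a cluster high in Notch genes and 2 ameloblast-like clusters differed in their signalling genes. The Ambn cluster (37.5% of epithelial cells) and the Dspp cluster (23.4%) were secretory ameloblast-like, and the Grp (27.0%) and Krt17 (12.1%) clusters met no naming rule. Grp cells, led by Grp, Pthlh and Sfrp5, had all 39 measured cycle genes at least 2-fold above the other epithelial cells, and 36.0 cycle UMIs per 10000 (35.2 to 36.7) against 1.21 in the Ambn cluster. FGF genes were higher in 9 of 11 cases and lower in 0 (median log2 2.96), led by the FGF feedback genes Spry4 (log2 5.14, 3.69 to 7.08) and Dusp6 (110 against 4.18 CPM, log2 4.72) and the FGF target Etv4 (log2 4.23). The WNT inhibitor Wif1 was lower (log2 −3.87). Ratios and counts in the epithelium use all UMIs, and their zero point is shifted: 95% of random lists matched to the cycle genes had medians of 0.18 to 0.78 in Grp, 0.16 to 0.67 in Krt17 and −1.06 to −0.50 in Ambn cells.

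Krt17 cells, led within the epithelium by Enpp2, Tnc and Nectin3, had 7 of 11 Notch genes higher and 1 lower (median 1.89), with Notch2 at 383 against 8.68 CPM (log2 5.47, 5.11 to 5.83), Notch3 at log2 5.26 and the Notch target Heyl at log2 4.64. The phosphatase Alpl stood at 993 against 6.51 CPM (log2 7.25, 6.88 to 7.66). IGF genes were higher in 4 of 8 cases and lower in 1, with Igfbp5 at 1291 against 54.4 CPM (log2 4.57), and Runx2 had 66.6 against 6.40 CPM (log2 3.38, 2.84 to 3.92). In the Dspp epithelial cluster Tgfb3 (87.8 against 1.44 CPM, log2 5.93) and Shh (574 against 212 CPM, log2 1.44) were higher. In the Ambn cluster Bmp2 (log2 2.84) and Wif1 (621 against 154 CPM, log2 2.01) were higher and Shh lower (63.9 against 470 CPM, log2 −2.88). All 4 clusters are marker-based groups from 1 sample.

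High Runx2, Igf1 and Igfbp3 in the Ogn cluster were weighed against 3 technical sources. Free RNA like that of droplets of 1 to 20 UMIs is argued against, since the lowest of the 3 ratios to it was 20.5 (17.5 to 24.1), for Igfbp3. Doublets with macrophages are argued against as the source of Igf1 because its level in the cluster was 12.4 times that in macrophages, which no mixture can reach. Scaled by this unattainable factor, macrophage C1qa, C1qb, C1qc and Cd68 would be so high that their median in the cluster was 8.40e-05 of it (3.82e-05 to 0.000161), so this ratio adds little. C1qa itself was scarce, at 4.00 CPM against 3565 CPM in macrophages. A minority of perivascular cells is argued against for Runx2, because 83.3% of the cluster's cells (79.2 to 86.9) had a Runx2 UMI at full depth, beside 20.7% to 34.5% in the other mesenchymal clusters of more than 100 cells. In the same direction, 72 cells without a UMI of 8 perivascular markers (median depth 3368.5 UMIs) had 8.54 times (6.95 to 10.4) the Runx2 level of other mesenchymal cells, 115 times the Igf1 level and 265 times the Igfbp3 level, though at their depth a missing UMI does not show that a cell is not perivascular. That the cluster as a whole is perivascular-like stays open, since Tagln and Acta2 lead it and most of its cells had a UMI of these markers. The cluster may also be a follicle-like population with its own Runx2 and IGF genes, a hypothesis that arose from this same sample and was not tested.

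Ambn was high relative to Amelx in the odontoblast-like Sct cluster, where the ratio of their UMIs was 0.683, beside 0.137 in macrophage-like cells and 0.155 in epithelial cells. Free RNA of ameloblasts would carry both genes in 1 ratio, but the Sct ratio was 4.98 times (4.40 to 5.63) that of macrophage-like cells, which argues against it as the only source. Ratios of 0.513 to 1.76 were seen in the mesenchymal clusters other than Hbb-bs (0.257) and Ogn (0.158). Doublets with epithelial cells would bring the epithelial ratio, which is also lower for the class as a whole. The ratio was not measured in single epithelial clusters, so doublets with one of them are not excluded. Mesenchymal cells other than the Ogn cluster may transcribe some Ambn themselves, a hypothesis that these counts alone cannot settle.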
